A study of Mus musculus with 6 samples.

How the data were processed

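ATRX, a SWI/SNF-family chromatin remodelling protein, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) with the H300 antibody. Per the labels' protocols, chromatin was fixed with EGS and then formaldehyde, a double crosslink used for proteins that touch DNA indirectly, and sonicated. The series holds 6 samples with 1 library in each group, so no group has a replicate. Of these, 2 were analysed here, each through a peak list: mouse embryonic fibroblasts (MEFs, cultured connective-tissue cells) of the C57BL/6 strain, and Ter119-selected erythroid cells of C57BL/6 foetal liver at embryonic day 14.5. The C57BL/6 MEF input, the ATRX and input libraries of the MEFs labelled W8, and the ATRX library of Suv39h1/2 knockout MEFs (Suv39h1 and Suv39h2 are histone H3 lysine 9 methyltransferases) make up the other 4 samples. They had no values of their own among the files used and were not analysed here.

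Reads were aligned with Bowtie 0.12.3 and the build is mm9, per the submitters' processing notes. The peak caller, its threshold, the control library used and any filter are not given in the sources used here. Whether regions that gather reads in any library, such as collapsed repeats, were removed is thus unknown, and with the inputs not analysed here such regions were not separated from ATRX binding. Each deposited file has 3 columns, which hold the chromosome, start and end of each peak, with no height, fold, score, p-value or read count. The depth behind each peak is therefore unknown, and no peak could be ranked by strength. Intervals below cover only the counting of peaks. The ends of 18 MEF peaks and 3 foetal liver peaks lie past the GRCm38 length of their chromosome and 0 lie past the mm9 length, so the files use mm9 positions. Starts are printed counted from 1.

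Chromosome lengths of mm9 came from the R package GenomeInfoDb 1.38.1. A gene table of another build (GRCm38.p6) was used only for the number of genes of each class per chromosome, in the closing section, and none of its coordinates were set against the peaks. The planned tests of genomic features, of gene lists and of the sequence under the peaks all need the mm9 annotation or sequence, and were not run. For the same reason no gene is named at a peak, and regions are given by position.

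Everything else was computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A peak was called shared if it overlapped a peak of the other list by at least 1 bp. Chance overlap came from 1000 random placements of the MEF peaks within their own chromosome, with widths kept and the unsequenced first 3 Mb left out. Clustering of peaks, defined as another peak of the list within 10 kb, was set against 1000 placements of that same list made in the same way. One-sided p-values from placements cannot fall below 0.001. Shares have exact Clopper-Pearson 95% intervals. Peak numbers per chromosome were tested against chromosome length by two-sided exact binomial tests, and between the lists by Fisher's exact tests, with Benjamini-Hochberg adjustment over 21 chromosomes and a threshold of 0.05. Peaks near chromosome ends were those with a midpoint in the last 1 Mb of the assembly, or in the first 1 Mb after the 3 Mb gap, on 20 chromosomes. Chromosome Y has no such gap, and its 3 MEF and 7 foetal liver peaks were left out of the end tests. Median widths were compared by two-sided permutation tests with 100000 resamples.

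These tests treat peaks as units. Peaks are not replicates and neighbours are not independent, so each p-value describes 1 library or a pair of libraries and says nothing about the spread between cultures or animals. The functions were tested on simulated data, 20 pairs of lists of the real sizes with planted effects and 20 without. Overlap, an excess on chromosome 10 and an excess at distal ends were called in 20 of 20 planted pairs each and in 0 of 20 unplanted pairs each. The planted pairs had 60 common peaks, a weight of 2 on chromosome 10 and 20 added distal peaks. Chromosomes other than 10 gave 1 false call in the 20 planted pairs and 1 in the 20 unplanted pairs. Clustering was not planted and was called in 2 of 20 planted and 0 of 20 unplanted pairs. Unplanted simulated peaks were placed independently of each other, whereas the real lists were clustered. The false calls therefore do not measure the error of these tests on the real lists.

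The rule for named regions, the tests of the report and most alternatives were chosen before the data were examined. In each list the 10 widest peaks, the 10 peaks nearest a distal end and the densest 1 Mb window were to be named, with the 10 widest shared regions, since the files hold no score. Alternatives were an overlap of 50% of the shorter peak, a distance of 1 kb or 10 kb, the wider 50% of each list, merging within 1 kb, other windows and distances, autosomes only, and genome-wide placement. Counting peaks within 100 kb or 1 Mb once, leaving out single chromosomes, and treating identical peaks apart were added after seeing the data, as were the clustering of peaks merged within 1 kb, the comparison of small gaps and the runs other than the densest window of each list.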

Results

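The series title concerns ATRX at transcribed telomeric repeats, and its samples set wild-type fibroblasts beside erythroid cells and fibroblasts without Suv39h1 and Suv39h2. The data analysed here were 2 ATRX peak lists from 1 library each, one from C57BL/6 MEFs and one from C57BL/6 erythroid foetal liver cells. The MEF list held 2054 peaks covering 2981 kb, or 0.112% of mm9. The foetal liver list held 983 peaks covering 933.3 kb, or 0.0352% of mm9. The files give no read counts, so the depth behind the peaks is unknown. The comparison that these lists allow is between the 2 cell types, and with 1 library per group it has no replicate check. The series holds inputs of MEFs only, so the control behind the foetal liver list, if any, is unknown. Differences between the lists cannot be told apart from differences in control, depth or library.

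MEF peaks were wider than foetal liver peaks. The median width was 1020 bp in MEFs (exact 95% interval 981 to 1065 bp, 2054 peaks) and 675 bp in foetal liver (650 to 709 bp, 983 peaks). The middle 50% of widths ran from 685 to 1652 bp in MEFs and from 466 to 989 bp in foetal liver. The narrowest peaks were alike, at 302 and 299 bp. Peaks over 5 kb numbered 63 in MEFs and 15 in foetal liver. The smallest gap between neighbouring peaks was 102 bp in MEFs and 282 bp in foetal liver, the latter between the shared pair on chromosome X described below, and the next smallest foetal liver gap was 853 bp.

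Few peaks were common to both cell types. In foetal liver, 61 of 983 peaks (6.21%, exact 95% interval 4.78 to 7.90%) overlapped a MEF peak. In MEFs, 64 of 2054 peaks (3.12%, 2.41 to 3.96%) overlapped a foetal liver peak. Random placement gave a mean of 2.10 shared foetal liver peaks and at most 8 in 1000 placements (one-sided permutation p = 0.001, the smallest that the placements can give). The observed number was thus 29.1 times the mean of chance placement. All 61 shared foetal liver peaks had a MEF peak with exactly the same start and end, and 0 overlapped a MEF peak with other boundaries. The overlap count therefore does not rest on boundaries measured separately in each list. The remaining 3 MEF peaks in the overlap lay inside such common regions, 1 on chromosome 1 and 2 on chromosome Y. With the identical peaks left out, 51 of the 922 remaining foetal liver peaks had one of the 1993 remaining MEF peaks within 10 kb, against a mean of 17.2 in placements (one-sided permutation p = 0.001, again the smallest possible). The placements spread MEF peaks singly and evenly along each chromosome, whereas the real peaks of both lists were clustered. Unrelated lists that crowd in the same stretches could exceed such placements, so neither p-value shows common binding by itself.

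The shared regions included 8 of the 10 widest foetal liver peaks and 3 of the 10 widest MEF peaks. The widest was on chromosome 1 (172993643 to 173014931, 21289 bp), the widest MEF peak and the second widest foetal liver peak. Next came 2 neighbouring regions near the distal end of chromosome X (166423463 to 166437580, 14118 bp, and 166437863 to 166447046, 9184 bp) and a region on chromosome 12 (55830712 to 55840314, 9603 bp). Chromosome Y (2689152 to 2697314, 8163 bp), chromosome 11 (87236488 to 87243402, 6915 bp), chromosome 19 (5813182 to 5819908, 6727 bp) and chromosome 16 (3231612 to 3238062, 6451 bp) followed. The last of the 10 widest shared regions were 2 neighbours on chromosome 1 (72300606 to 72306712, 6107 bp, and 72271843 to 72277749, 5907 bp). Of the foetal liver peaks over 5 kb, 13 of 15 were shared, and of the MEF peaks over 5 kb, 13 of 63 were. The shared median width in foetal liver was 1716 bp against 650.5 bp for the other 922 peaks, a difference of 1066 bp (two-sided permutation test over peaks, p = 2e-05, the smallest it can give). In MEFs it was 1713 bp against 999.5 bp for the other 1990, a difference of 713.5 bp (p = 2e-05 by the same permutation test). The permutation allows neither for wider peaks meeting a 1 bp overlap more often nor for the identical boundaries, so these p-values do not show that shared sites were wider before any joining. The 2 differences also do not rest on separate measurements. Among the wider 50% of each list the MEF difference was 206 bp (permutation p = 0.199).

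Wide peaks outside the shared set are absent from the other list by definition. In foetal liver the widest peak of all lay on chromosome 19 (5825903 to 5848706, 22804 bp), about 6 kb distal to the shared region there, and was not in the MEF list. The only other unshared foetal liver peak among its 10 widest was on chromosome 4 (135729160 to 135736568, 7409 bp). In MEFs, 7 of the 10 widest peaks were unshared. These were on chromosome 2 (157376956 to 157393095, 16140 bp), chromosome 11 (11918390 to 11930357, 11968 bp), chromosome 8 (79966910 to 79976700, 9791 bp), chromosome 6 (34651073 to 34660725, 9653 bp) and at 3 sites on chromosome 10. The chromosome 10 sites were 107807804 to 107821113 (13310 bp), 122412477 to 122422868 (10392 bp) and 122325498 to 122335017 (9520 bp).

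**Figure D1:**
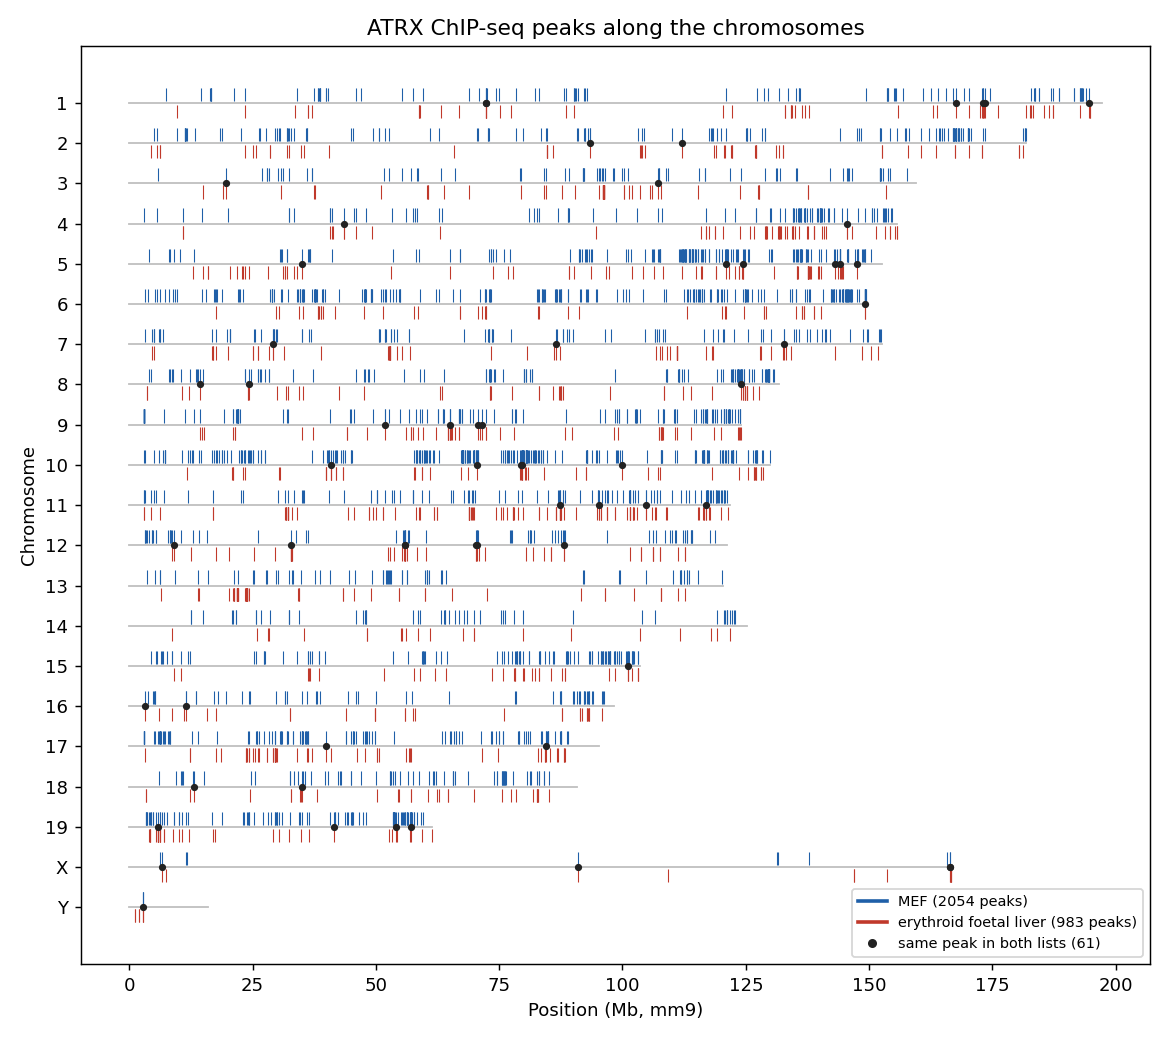
Positions of all ATRX peaks on the mm9 chromosomes (x axis in Mb, y axis chromosome), with MEF peaks as ticks above each line, foetal liver peaks as ticks below it and the 61 peaks with the same boundaries in both lists as dots. Chromosomes 6 and 10 carried many MEF peaks and chromosome X few peaks of either list, 11 and 12.

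ATRX peaks were spread unevenly over the chromosomes, and differently in the 2 lists. In MEFs, chromosome 10 held 225 peaks where its length would give 100.6, a ratio of 2.24 (exact 95% interval 1.97 to 2.53; exact binomial test, adjusted p = 2.6e-27). Chromosome 19 followed with 103 peaks and a ratio of 2.17 (1.78 to 2.62; adjusted p = 6.1e-12, same exact test), and chromosome 6 with 203 peaks and a ratio of 1.75 (1.53 to 2.00; adjusted p = 1.7e-13). In foetal liver, chromosome 11 held 104 peaks where its length would give 45.1, a ratio of 2.31 (1.90 to 2.76; exact binomial test, adjusted p = 9.8e-14). Chromosomes 19, 17 and 13 of foetal liver had ratios of 1.59, 1.50 and 1.48. Adjusted p-values from the exact binomial test were 0.027, 0.019 and 0.011 in that order. Among the wider 50% of peaks, chromosomes 19 and 17 lost their call (1.41 and 1.59, exact test, adjusted p = 0.46 and 0.085). The chromosome 17 ratio did not fall there, and fewer peaks were tested (492 rather than 983). With peaks within 100 kb counted once, chromosomes 19 and 13 lost their call (1.53 and 0.751, exact test, adjusted p = 0.13 and 0.40).

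Of 21 chromosomes, 7 were above and 10 below their length share in MEFs, and 4 above and 2 below in foetal liver. The low MEF chromosomes include Y, with 3 peaks, all within a single shared region, where its full length would give 12.3. Unsequenced parts of chromosome Y were not taken out of that length. Among the wider 50% of MEF peaks, 10 rather than 17 chromosomes were off their share, and with MEF peaks within 100 kb counted once 13 were. Chromosome X was low in both lists, with 11 MEF peaks (ratio 0.0853, interval 0.0426 to 0.152) and 12 foetal liver peaks (0.194, 0.101 to 0.338). Of these, 4 in each list were the same regions. The length share counts every chromosome as equally copied, and the copy number of X was not examined. Chromosome 14 was also low in both, with ratios of 0.537 in MEFs and 0.475 in foetal liver. With peaks within 100 kb counted once the foetal liver call on chromosome 14 was lost (0.572, exact test, adjusted p = 0.051), and with 1 Mb it was lost in both lists (0.8002 and 0.8307, exact test, adjusted p = 0.82 each).

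Between the lists, 4 chromosomes differed by Fisher's exact test. Chromosomes 6 and 10 held a larger share of MEF peaks, with odds ratios of 2.29 and 2.16 (exact test, adjusted p = 1.9e-06 each). Chromosomes 11 and 13 held a larger share of foetal liver peaks, with odds ratios of 0.464 and 0.418 for MEF over foetal liver (exact test, adjusted p = 1.9e-06 and 1.2e-05). When peaks within 100 kb were counted once, chromosomes 6, 10 and 11 still differed (odds ratios 2.07, 1.75 and 0.615, exact test, adjusted p = 0.0017, 0.020 and 0.035). Chromosome 13 did not (0.913, exact test, adjusted p = 0.98), its foetal liver ratio to length was 0.751 instead of 1.48, and 3 rather than 6 foetal liver chromosomes were off their length share, without 13, 14 and 19. When peaks within 1 Mb were counted once, 0 chromosomes differed between the lists and chromosome X was the only one off its length share in either list. That setting chained the lists into 583 MEF and 434 foetal liver stretches and joined most peaks of a dense chromosome. Calls lost at 1 Mb, here and for chromosome 14, therefore do not show that a difference was absent.

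**Figure D2:**
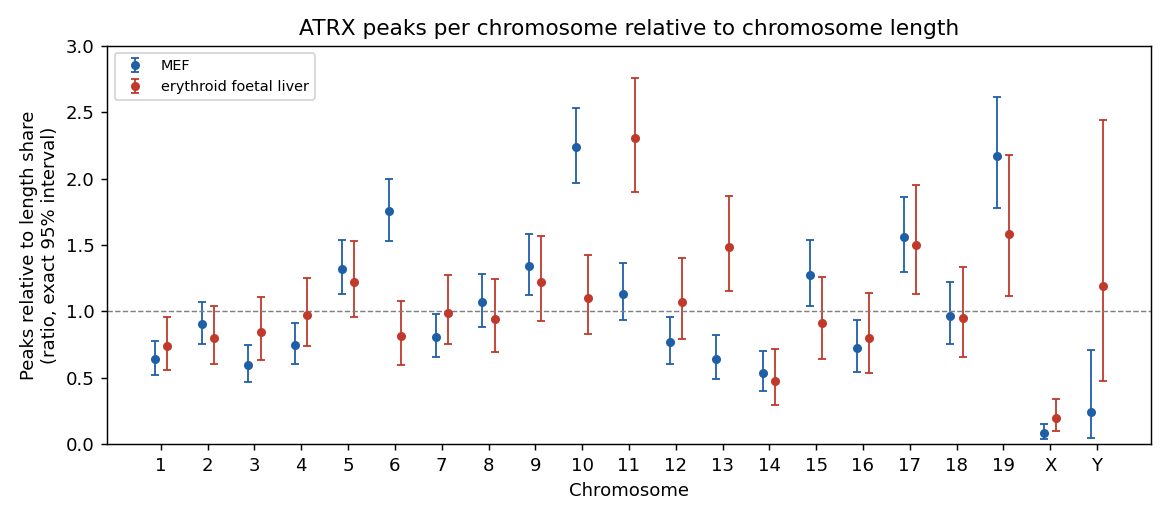
Number of ATRX peaks on each chromosome (x axis) divided by the number its mm9 length would give (y axis, ratio), with exact 95% intervals that cover the counting of peaks only; 1 library per cell type. MEF points stand highest on chromosomes 10 and 19 (2.24 and 2.17) and the highest foetal liver point is on chromosome 11 (2.31).

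Peaks had a neighbour within 10 kb more often than placed peaks did. The densest windows of the lists are given with the peaks of the other list in them, and a difference between the lists in these windows was not tested. In foetal liver, 185 of 983 peaks (18.8%, exact 95% interval 16.4 to 21.4%) had another peak within 10 kb, against 0.964% on average in placements (one-sided permutation p = 0.001, the smallest possible). In MEFs it was 266 of 2054 peaks (12.95%, 11.5 to 14.48%), against 2.26% in placements (permutation p = 0.001, likewise). Within 1 kb the MEF list kept its excess (9.23 times placement, permutation p = 0.001) and the foetal liver list did not (4 of 983 peaks, 2.31 times placement, permutation p = 0.21). The smallest foetal liver gaps were 282 and 853 bp, so that list had few gaps to count within 1 kb. This contrast cannot tell clustering of binding from how each list was built. The densest foetal liver window held 25 peaks on chromosome 13 (23529364 to 24251904) and 0 MEF peaks. The following foetal liver runs were chosen after their values were seen. The second held 16 peaks on chromosome 3 (95323056 to 96307308), with 3 MEF peaks where that list averaged 0.464 per Mb of the chromosome, and the third 14 peaks again on chromosome 13 (21261257 to 22142763), with 2 MEF peaks. A foetal liver run of 10 peaks lay on chromosome 19 (5407197 to 6300896), with 4 MEF peaks. Windows of 9 foetal liver peaks lay on chromosome 11 (31670817 to 32197563 and 68854324 to 69809290) and chromosome 17 (29043824 to 29997554), with 0, 2 and 3 MEF peaks. On chromosomes 13, 19, 11 and 17 the MEF list averaged 0.499, 1.68, 0.878 and 1.21 peaks per Mb.

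The densest MEF window held 17 peaks on chromosome 10 (79550816 to 80550192), with 5 foetal liver peaks where that list averaged 0.408 per Mb of the chromosome. The other MEF runs described here were likewise chosen after their values were seen. The second was a run of 15 MEF peaks packed into 38.6 kb of chromosome 9 (3000002 to 3038625), starting at the first base pairs of sequence after the 3 Mb gap, with 0 foetal liver peaks. Whether regions prone to artefacts were removed from the lists is unknown, which limits this run, the peaks it adds near the gap and the shared regions alike. A second chromosome 10 window held 14 peaks (67158287 to 68159263), with 1 foetal liver peak.

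Mouse chromosomes are acrocentric, so the assembly ends at the telomere-side (distal) end, and the first sequence after the gap lies on the centromere side. The lists hold no sequence, so telomeric repeats themselves were not analysed here. Peaks in distal ends exceeded their length share in both lists, in MEFs not under every setting. In foetal liver, 21 of 976 peaks (2.15%, exact 95% interval 1.34 to 3.27%) lay in the last 1 Mb of a chromosome, where length would give 0.775%, a ratio of 2.77 (exact binomial test, p = 4.0e-05). In MEFs, 29 of 2051 peaks did (1.41%, 0.949 to 2.02%), a ratio of 1.82 (p = 0.0023, same exact test), but 10 of the 29 were on chromosome 6. Without chromosome 6 the MEF ratio was 1.32 (exact p = 0.23), and with peaks within 100 kb counted once it was 1.17 (exact p = 0.56). The corresponding foetal liver ratios were 2.61 and 2.57. The excess in both lists depended on the window: in the last 0.5 Mb the ratios were 3.02 in MEFs (exact p = 3.2e-06) and 4.76 in foetal liver (exact p = 1.0e-07). In the last 5 Mb they were 2.36 in MEFs (188 peaks, exact p = 2.1e-26) and 1.53 in foetal liver (58 peaks, exact p = 0.0016). The odds ratio of foetal liver over MEF was 1.53 (Fisher's exact test, p = 0.17). Without chromosome 6 it was 2.01 (p = 0.037, same exact test), and in the last 5 Mb it turned to 0.626 (p = 0.0022, same exact test). Of the 21 foetal liver peaks, 5 were on chromosome X, without which the ratio was 2.11 (exact p = 0.0054).

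The outermost peaks reached the end of the assembled sequence. A MEF peak on chromosome 2 (181746821 to 181748087) ended on the last base of the assembly, 0 kb from it. A foetal liver peak on chromosome 4 (155629651 to 155630056) ended 0.064 kb from the end. Other MEF peaks within 100 kb of an end were on chromosome 7 (24.7 kb from it), chromosome 10 (32.03 kb), chromosome 13 (66.9 kb) and chromosome 2 (82.4 and 84.8 kb). In foetal liver they were on chromosome X (18.6, 39.2 and 68.9 kb), chromosome 9 (22.99 kb), chromosome 4 (52.8 kb) and chromosome 19 (58.5 kb). None of these 13 peaks was in both lists. The nearest shared regions were the neighbours on chromosome X, 203.3 and 212.7 kb from the end. The remaining peaks among the 10 nearest were 2 MEF peaks on chromosome 6 (149308685 to 149312353 and 149307401 to 149308298, 204.7 and 208.7 kb from the end) and a foetal liver peak on chromosome 9 (123760829 to 123761686, 314.5 kb).

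The centromere-side start of the sequence was overrepresented in MEFs. There, 44 of 2051 MEF peaks (2.15%, exact 95% interval 1.56 to 2.87%) lay in the first 1 Mb after the gap, a ratio of 2.77 to the expected 0.775% (exact binomial test, p = 4.4e-09). In foetal liver 8 of 976 did (0.820%, 0.355 to 1.61%), a ratio of 1.06 (exact p = 0.85), and the lists differed (odds ratio of foetal liver over MEF 0.377, Fisher's exact test, p = 0.0070). The MEF ratio was 4.65 in the first 0.5 Mb (exact p = 5.5e-14) and 1.58 in the first 5 Mb (exact p = 7.7e-07). Of the 44 MEF peaks, 15 made up the chromosome 9 run and 7 lay within 100 kb of the gap on chromosome 17 (3006569 to 3083415), a run also chosen after its values were seen. Without chromosome 9 the MEF ratio was 1.95 (exact p = 9.4e-04) and the odds ratio 0.573 (Fisher's exact p = 0.21). With peaks within 100 kb counted once, the MEF ratio was 1.51 (exact p = 0.080) and the odds ratio 0.728 (Fisher's exact p = 0.66).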

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

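All tests of explanations in this part were chosen after the results were seen. The share of peaks on 4 chromosomes differed between the lists, with odds ratios of MEF over foetal liver of 2.29 on chromosome 6, 2.16 on chromosome 10, 0.464 on chromosome 11 and 0.418 on chromosome 13 (Fisher's exact tests). The chromosome 13 difference was lost with peaks within 100 kb counted once (0.913, exact test, adjusted p = 0.98), and with 1 Mb all 4 were. Counting within 1 Mb joins most peaks of a dense chromosome, so the loss of all 4 does not show that the differences were absent. The share of peaks just after the centromere-side gap differed between the lists too, with an odds ratio of foetal liver over MEF of 0.377. That difference lost its call without chromosome 9 (0.573, exact p = 0.21) and with peaks within 100 kb counted once (0.728, exact p = 0.66). Among the wider 50% of peaks the call was also lost (0.328, exact p = 0.067), but the odds ratio was no closer to even and fewer peaks were tested.

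For the excess of MEF peaks on chromosomes 10 and 6, gene density as the whole cause is argued against: relative to their share of protein-coding genes (GRCm38.p6) the smaller of the 2 lower bounds was 1.68. A few dense stretches are argued against as well, since without the 2 densest 10 Mb bins of each chromosome the ratios to length were 1.99 and 1.61, with a smaller lower bound of 1.38. With peaks within 1 Mb counted once the ratios fell to 1.09 and 1.28 (exact test, adjusted p = 0.82 and 0.74), a setting that joins most peaks where they average 1.73 and 1.36 per Mb. Extra copies of whole chromosomes in the cultured fibroblasts remain a candidate explanation, which the bins cannot decide. MEF peaks exceeded the genome mean in 10 of 12 bins of chromosome 10 and 11 of 14 bins of chromosome 6. The chromosome 6 share (78.6%) was just under the bound of 80% set for this test. Any excess along a whole chromosome, whatever its cause, would raise most bins in the same way. Copy number would show in the MEF input reads, which were not analysed here, and a difference between the cell types in ATRX binding stays open and untested.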

How the results depend on the processing

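Leaving out identical peaks or single chromosomes and counting peaks within 100 kb or 1 Mb once were chosen after seeing the data. The planned annotation, gene-list and sequence tests were not run, for want of mm9 annotation and sequence, and neither were their alternatives. Depth is unknown, so its effect could not be examined. Over 46 results and 246 alternatives, 176 kept direction and side of the threshold (or stayed within their limit), 13 moved, 39 kept direction and lost their call, 2 kept direction and gained one, and 16 turned direction, with or without a change of call. Some alternatives could not move a value, so the 176 overstate how stable the results are. Lengths without the 3 Mb gap cannot change a chromosome's odds ratio between the lists, and genome-wide placement cannot change an observed overlap count. At distal ends, leaving out chromosome X is the same test as autosomes only. The causes of changes were not tested except where named. By construction, the wider 50% of each list left 1027 and 492 peaks with medians of 1652 and 989 bp. It left 10 rather than 17 MEF chromosomes off their length share, a shared-minus-specific MEF width of 206 bp, a proximal foetal liver ratio of 0.793 and a proximal odds ratio of 0.328 (exact p = 0.067). With fewer peaks a call is harder to reach, so a call lost there need not mean a weaker effect. Allowing 10 kb raised the shared peaks to 118 in each list. Leaving out identical peaks gave 0, because all 61 overlapping foetal liver peaks were identical to a MEF peak. Within 1 kb, the foetal liver clustering was 2.31 times placement (one-sided permutation p = 0.21), where the list has few gaps that small. Counting peaks within 100 kb once left 3 foetal liver chromosomes off their share instead of 6, a chromosome 13 foetal liver ratio of 0.751, a distal MEF ratio of 1.17, a distal odds ratio of 2.22 (exact p = 0.040), a proximal MEF ratio of 1.51 and a proximal odds ratio of 0.728. Without chromosome 6 the distal MEF ratio was 1.32 and the distal odds ratio 2.01; without chromosome 9 the proximal odds ratio was 0.573; without chromosome 17 the proximal foetal liver ratio was 0.993. In a 5 Mb window the distal odds ratio turned to 0.626 (exact p = 0.0022) and the proximal foetal liver ratio to 0.951. Counting peaks within 1 Mb once chained them into 583 MEF and 434 foetal liver stretches, which joins most of a dense chromosome. It left 1 chromosome off its share in each list, 0 that differed, and MEF ratios of 1.06 (chromosomes 1, 13), 1.07 (16), 1.05 (4), 1.04 (7), 0.925 (5) and 0.965 (19). The foetal liver ratio of chromosome 13 was 0.915, and odds ratios were 0.959 (10), 1.02 (11) and 1.17 (13). Chromosome X stayed low in both lists under each setting run on chromosomes.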

Other observations

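Each test in this part was chosen after the data were seen. Across 20 chromosomes, Y left out, peaks per Mb of mm9 rose with protein-coding genes per Mb of GRCm38.p6, counted separately in each build. Chromosomes are not replicates. In foetal liver, Pearson's r was 0.628 (permutation p = 0.0031, adjusted over 2 relations 0.0062) and Spearman's rho 0.573 (permutation p = 0.0095, adjusted 0.0098). In MEFs, r was 0.3805 (permutation p = 0.097, adjusted 0.097) and rho 0.571 (permutation p = 0.0098, adjusted 0.0098). Without chromosomes 7 and 11, the farthest from the median gene density, r was 0.618 in foetal liver and 0.626 in MEFs. Chromosome X lay far below the rest, with 0.121 MEF and 0.277 foetal liver peaks for each peak expected from its share of protein-coding genes.

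One hypothesis is that the foetal liver runs on chromosomes 13 and 3 may follow histone gene clusters, since 56 of 71 genes with a Hist symbol or synonym in GRCm38.p6 are on chromosome 13 and 10 on chromosome 3. The densest 1 Mb windows of the foetal liver list held 25 and 16 peaks on these chromosomes and at most 10 on any other. The densest MEF windows on these chromosomes, found separately in the MEF list, held 5 and 6 peaks. In 1000 placements the highest window held 8. Of these placements, 50 had their densest windows on both chromosomes, ties counted (5.09% with the observed list included), so the match of chromosomes alone does not exclude chance. The test at first had no such condition, and the condition of under 5% was added after the value was seen. The hypothesis stays open, since no mm9 gene positions were used: none of 13 gene classes of the table has chromosomes 13 and 3 as the 2 with most genes, but 105 of 408 tRNA genes are on chromosome 13 and 40 on chromosome 3.

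The 61 overlapping foetal liver peaks all had the boundaries of a MEF peak, and 0 overlapped one with other boundaries. These counts argue against boundaries set separately in each list at these 61 peaks. Joint boundaries set before deposit are a candidate explanation, but the counts are the observation that raised it and do not test how it was done. The 3 MEF peaks that stayed separate inside them argue against a plain merge of all overlapping peaks, and how the boundaries were set stays open. Whether one merging distance was used for both lists stays open: gaps under 850 bp made up 29.9% of MEF and 0.952% of foetal liver gaps under 10 kb (Fisher's exact test, p = 4.3e-11), but that bound was read off the foetal liver gaps, so the test decides nothing. Merging both lists within 1 kb left 2002 MEF and 981 foetal liver peaks, median widths of 1041.5 and 675 bp, and a clustering of 4.22 and 19.2 times placement. Binding at the same sites in both cell types remains open for the 61 regions, since the original boundaries were not analysed here.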
